A study of Homo sapiens with 7 samples.

How the data were processed

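Poly(A) 3' end mRNA libraries and 1 small RNA library of HCT116 cells, a human colorectal carcinoma line, were used. The mRNA libraries came from cells with a DROSHA knockout that had been transfected with a control miRNA (3 libraries) or with miR-148a-3p (3 libraries). Per the labels' protocols, RNA was taken 48 h after transfection and 500 ng of total RNA was primed with oligo-dT, so reads lie near the 3' ends of transcripts and do not scale with transcript length. The small RNA library came from wild-type HCT116 cells and was prepared with the TruSeq small RNA kit, per the labels' protocols.

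The authors deposited raw read counts per gene symbol for each mRNA library, with no normalization. Genes without a read in a library were missing from its list and were read as 0. Per the submitters' processing notes, cutadapt, STAR and Bowtie2 and the GRCh38 build were used; which tool served which assay, their versions, the counting tool, the annotation and the use of strand are not given in the sources used here. The deposited small RNA values were counts per isoform, each with the offset of its 5' and 3' end from the annotated mature microRNA, per the file header. Isoforms with a blank count (4409 carried a count) were left out. Of 15659 gene symbols, 15486 matched a current symbol and 170 an older symbol in the gene name tables, and 3 matched neither. Gene coordinates are the RefSeq gene spans of a GRCh38 patch release, the build named in the notes, and give no exon or untranslated region. Oligo-dT libraries can also count reads of pseudogenes, readthrough genes and overlapping genes under another symbol. Of the symbols listed, 0 started with MT-, the prefix of genes encoded by the mitochondrial genome, so these genes were not analysed here. Older names without that prefix were not searched for.

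Counts were tested with edgeR 4.0.16 in R 4.3.3, using TMM normalization, filterByExpr with the group (8921 genes kept) and the quasi-likelihood F test, with the group as the only term. P-values were adjusted by the Benjamini-Hochberg method over all genes tested, and an adjusted p below 0.05 was the threshold. Log2 fold changes are miR-148a-3p over control and are given with their standard errors (SE). Expression levels are TMM-normalised CPM values, counts scaled to a common library size, as mean ± SD over 3 libraries. With 3 libraries against 3, an exact permutation test of 1 value cannot give a two-sided p below 0.1, so no such test was used for a single gene. The labels do not say that replicates were separate cultures, so p-values measure only the spread between these libraries, which may be technical. Pairs of libraries within a group differed by 2.65 to 6.73 times the variance of Poisson sampling (chi-square per degree of freedom), more than sequencing 1 library again would give; repeat preparations of the same RNA are not excluded.

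Before the data were examined, 19 gene lists were fixed, among them direct targets of the miR-148 family (miR-148a, miR-148b and miR-152) written down from memory, microRNA pathway genes, deadenylation and decapping factors, apoptosis, cell cycle and signalling genes, and markers of blood cells, of fibroblasts and endothelium, and of colon epithelium. The 16 lists with at least 3 tested members were compared with all other genes by camera in limma 3.58.1, with a preset correlation of 0.01 and Benjamini-Hochberg adjustment over the lists. Camera with an estimated correlation and fry, which asks whether the members of a list move one way on balance, were run beside it. The rule for the genes named, fixed at the same time, took up to 10 genes per direction among those past the threshold with a mean of at least 10 CPM and no overlap between groups, the 3 genes with the smallest p in each direction, DROSHA and DDX6, and up to 4 members of each list with the smallest p. Other genes named were chosen after their values were seen, and the text says so.

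MicroRNA levels are shares of all microRNA counts, with Wilson 95% intervals from scipy 1.17.1. Reads were not collapsed to molecules, so these intervals cover counting error only. RefSeq loci of each microRNA were counted by symbol. The scripts were tested on simulated counts drawn for the 8921 genes from the libraries' means and sizes. In 5 such simulations of the comparison, 43.6% of genes changed by 1 on the log2 scale were called, 87.3% of those changed by 2, 5.97% of those changed by 0.5, and 0.0345% of unchanged genes. Over the 5 simulations, 335 genes were changed by 0.5, 335 by 1 and 330 by 2, and the listed miR-148 family targets were shifted by −0.25. The adjusted threshold is stricter where fewer genes change. The real fit called 1 gene, so these shares may be too high for it.

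The alternatives tried were other size factors (DESeq2's and upper quartile), DESeq2 1.42.0 and limma-voom as tests, other filters on low counts, counts without the 10 most abundant genes, the replicate number as a block, thinning to the smallest library, and each library left out in turn. After the data were seen, offsets for gene length and chromosome, summed reads of overlapping or near-identical genes, and microRNA counts divided by the number of loci were added. Gene length is the RefSeq gene span, introns included, not the length of the transcript. The planned comparison of genes with and without a miR-148a-3p seed site in the 3' untranslated region needs transcript sequence, which was not used here, and it was not run.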

Results

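The transcriptome of DROSHA knockout HCT116 cells was compared between cells given miR-148a-3p and cells given a control miRNA, with 3 libraries in each group. DROSHA is the nuclear enzyme that cuts primary microRNA transcripts, so cells without it make few canonical microRNAs of their own. The series' title links miR-148a-3p with DDX6, a DEAD-box RNA helicase of mRNA decapping and microRNA repression, in myeloid leukemia cells; the libraries analysed here are from a colorectal line. The control libraries held 1069154, 876131 and 890849 counts, and the miR-148a-3p libraries 1564125, 842294 and 630142, over 12448 to 13849 genes each. The nuclear noncoding RNA MALAT1 was the most abundant gene in every mRNA library, at 0.937% to 1.75% of counts. The small RNA library of wild-type cells held 3627859 counts over 1023 microRNA names. It has no replicate.

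DROSHA itself was counted at 22.2 ± 6.60 CPM in the control group and 17.4 ± 4.12 CPM in the miR-148a-3p group (SD, n = 3), from 31, 16 and 16 reads and from 20, 15 and 13 reads. The knockout is in both groups and the labels do not say which part of the gene (chromosome 5, 31400494 to 31532093) was deleted, so reads near the 3' end check neither the knockout nor the labels. The log2 fold change was −0.40 (SE 0.43, edgeR adjusted p = 0.893).

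With miR-148a-3p, MORF4L1 fell to 0.319 of its control level, and it was the 1 gene of 8921 that passed the threshold. MORF4L1 encodes a chromodomain protein of histone acetyltransferase and deacetylase complexes. It was measured at 814 ± 272 CPM with the control and 260 ± 40.3 CPM with miR-148a-3p (SD, n = 3), lower in 3 of 3 libraries than in any control library. Its log2 fold change was −1.65 (SE 0.21, edgeR adjusted p = 1.56e-04), and its gene lies on chromosome 15, from 78872890 to 78898139. DDX6 was measured at 178 ± 18.7 CPM with the control and 106 ± 23.1 CPM with miR-148a-3p and did not pass over all genes tested.

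The reads of MORF4L1 may be shared with MORF4L1P1, a pseudogene chosen for mention after its values were seen, which had a log2 fold change of −0.86 (SE 0.26, edgeR adjusted p = 0.398). With the reads of both added, the sum was 933 ± 227 CPM with the control and 325 ± 32.9 CPM with miR-148a-3p, a log2 fold change of −1.52 (SE 0.19, edgeR adjusted p = 7.91e-05).

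No gene was higher past the threshold with edgeR, and DESeq2 and limma-voom also called 0 genes higher. Without the count filter, edgeR called 18 genes of 15659, 11 lower and 7 higher. At an unadjusted p below 0.05, 303 genes were lower and 303 higher, where 446 of 8921 are expected in all by chance. DESeq2 gave 447 such genes of 8921 (225 lower, 222 higher) and limma-voom 612. With edgeR, 405 of 9373 remained without miR-148a-3p replicate 3 and 470 of 9329 without miR-148a-3p replicate 2. Leaving out any other single library gave 614 to 745. An excess over chance thus depended on the test and the libraries. The groups did not overlap for 588 genes that were lower and 555 that were higher, 12.8% of those tested, where chance gives 10%. The median log2 fold change was −0.0039, and 98.3% of genes lay within 1 of 0. Without control replicate 1, which stood apart from the other libraries on the first principal component (−29.4, against −3.98 to 22.5, with 31.9% of the variance), edgeR called 26 genes, 22 lower and 4 higher. MORF4L1 was among them.

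**Figure D1:**
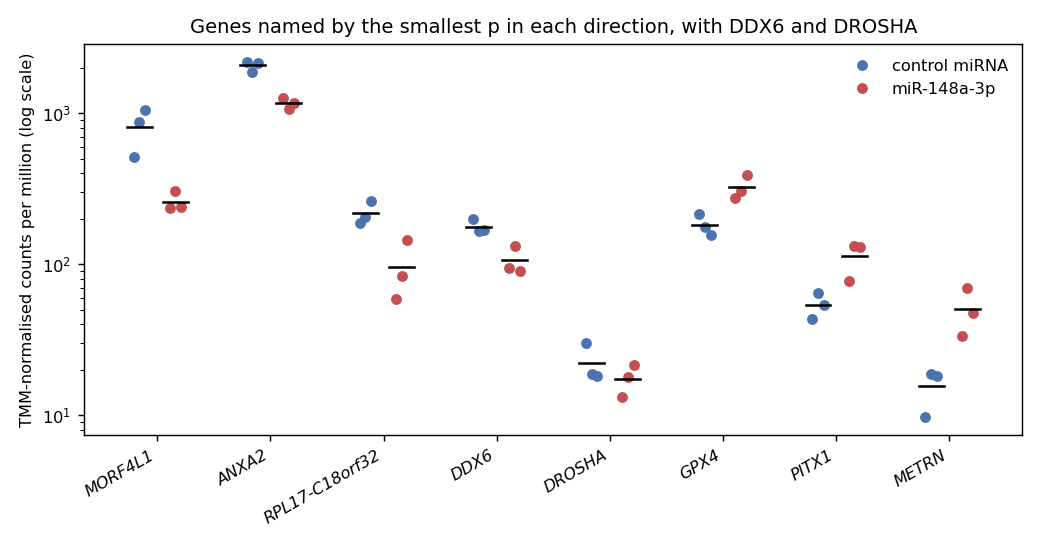
TMM-normalised CPM on a log axis for 8 genes in each mRNA library, with the mean of each group as a bar (control miRNA in blue, miR-148a-3p in red). MORF4L1 lies between 517 and 1052 CPM in the control libraries and between 235 and 306 CPM with miR-148a-3p.

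The genes next in rank by p did not pass. Among those lower with miR-148a-3p, ANXA2, a calcium-dependent membrane-binding protein (chromosome 15, 60347151 to 60397986), was measured at 2080 ± 174 CPM in the control group and 1169 ± 96.9 CPM with miR-148a-3p, a log2 fold change of −0.83 (SE 0.16, edgeR adjusted p = 0.0687). It passed with DESeq2 (adjusted p = 1.16e-04) and with limma-voom (adjusted p = 0.0232), and with edgeR after thinning (adjusted p = 0.0397). RPL17-C18orf32, a readthrough gene that overlaps the ribosomal protein gene RPL17, was measured at 218 ± 39.8 and 95.8 ± 44.3 CPM (log2 fold change −1.24, SE 0.25, edgeR adjusted p = 0.0933). With the reads of RPL17 added, its log2 fold change was −0.21 (SE 0.18, edgeR adjusted p = 0.870). Among genes with the smallest p on the higher side, METRN, a secreted neurotrophic factor (chromosome 16, 715118 to 719655), was at 15.5 ± 5.09 and 50.4 ± 18.2 CPM (log2 fold change 1.69, SE 0.38, edgeR adjusted p = 0.169). GPX4, the glutathione peroxidase that reduces lipid peroxides (chromosome 19, 1103994 to 1106779), was at 183 ± 30.5 and 325 ± 60.3 CPM (0.81, SE 0.20, adjusted p = 0.298). PITX1, a homeobox transcription factor (chromosome 5, 135027734 to 135034789), was at 53.7 ± 10.4 and 113 ± 30.6 CPM (1.06, SE 0.26, adjusted p = 0.311). Without control replicate 1, edgeR called ANXA2 (adjusted p = 0.00139), RPL17-C18orf32 (adjusted p = 1.85e-04) and GPX4 (adjusted p = 0.00684), and without miR-148a-3p replicate 3 it called RPL17-C18orf32 (adjusted p = 0.00591). RPL17-C18orf32 also passed with limma-voom (adjusted p = 0.0245) and with offsets for gene length and chromosome (edgeR adjusted p = 0.0230). Without the count filter, all 5 of these genes passed with edgeR (adjusted p = 0.00225 for ANXA2, 6.31e-05 for RPL17-C18orf32, 0.0160 for METRN, 0.0424 for GPX4 and 0.0424 for PITX1).

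DDX6 (chromosome 11, 118747763 to 118791744) was at 0.596 of its control level with miR-148a-3p, with a log2 fold change of −0.75 (SE 0.21), and it was lower in 3 of 3 libraries. The edgeR adjusted p was 0.322 over all genes tested, and the log2 fold change stayed between −0.93 and −0.66 with 1 library left out. Of the 30 tested genes of deadenylation and decapping, 17 had a lower and 13 a higher fitted value, 0 passed over all genes tested, and DDX6 was the 1 that passed adjusted over the list alone (adjusted p = 0.0423). Because the series' title names DDX6, that count is not independent evidence. It was lost, with adjusted p over the list alone from 0.0707 to 0.392, on leaving out any of the 3 control libraries or miR-148a-3p replicate 1 or 3, and on thinning (0.0569). EDC4, a scaffold of the decapping complex, had −0.71 (SE 0.32), CNOT6, a deadenylase, −0.56 (SE 0.25), and LSM7, of the LSM ring, 0.49 (SE 0.23). The list as a whole had a median of −0.02 and did not pass (camera adjusted p = 0.520).

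The known targets of the miR-148 family were lower as a group. Of 36 genes listed, 24 were tested, and 22 of them had a lower fitted value with miR-148a-3p, while ACVR1 and KLF6 had higher ones. Their median log2 fold change was −0.25, and the difference from the median of all other genes was −0.244 (camera adjusted p = 0.0163, and 0.682 with an estimated correlation). With fry, which tests the members against no change rather than against other genes, the adjusted p was 0.411. With edgeR, 0 members passed over all genes tested, 0 adjusted over the list alone and 0 at an unadjusted p below 0.05. PRKAA1, a catalytic subunit of AMP-activated kinase, had −0.74 (SE 0.39), QKI, an RNA-binding protein, −0.45 (SE 0.24), CDC25B, a phosphatase that activates cyclin-dependent kinases, −0.40 (SE 0.23), and CAND1, an exchange factor of cullin ligases, −0.36 (SE 0.22). DNMT1, the maintenance DNA methyltransferase, was measured at 266 ± 45.6 CPM with the control and 224 ± 22.5 CPM with miR-148a-3p. The mean of the list, relative to all 6 libraries, was 0.297, −0.080 and 0.111 in the control libraries and 0.014, −0.095 and −0.246 with miR-148a-3p. The call was lost without control replicate 1, where the difference was −0.11 (adjusted p = 0.171), and without miR-148a-3p replicate 3 (−0.20, adjusted p = 0.126).

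Genes of the G1/S transition were higher as a group, with 20 of 26 tested members higher and a median log2 fold change of 0.28 (camera adjusted p = 0.00427; adjusted p = 0.682 with an estimated correlation, and 0.634 with fry). MCM2, a subunit of the replicative helicase, was measured at 81.3 ± 45.7 and 153 ± 49.2 CPM (0.91, SE 0.31), CDT1, which loads that helicase, at 56.5 ± 9.19 and 94.8 ± 27.3 CPM (0.72, SE 0.26), and MCM6 at 64.9 ± 20.1 and 104 ± 51.3 CPM (0.65, SE 0.31). With edgeR 0 members passed over all genes tested or adjusted over the list alone, and 3 had an unadjusted p below 0.05. The list's mean was lower in replicate 1 of both groups (−0.435 in the control and −0.275 with miR-148a-3p) than in the other libraries (0.069 and −0.057 in the control, 0.351 and 0.347 with miR-148a-3p). The call was lost without control replicate 1 (difference 0.11, adjusted p = 0.171), miR-148a-3p replicate 2 (0.19, adjusted p = 0.212) or miR-148a-3p replicate 3 (0.17, adjusted p = 0.139). The replication histones showed the same low libraries (−0.472 and −0.527 in replicate 1), and 4 of 6 tested genes were higher, led by H4C3 at 0.63 (SE 0.23), with camera adjusted p = 0.263 (0.00247 without miR-148a-3p replicate 1). Their messenger RNAs lack a poly(A) tail, and the list was fixed as a sign of RNA selection. In oligo-dT libraries it is therefore not a clean measure of the cell cycle. Of the G2/M genes 21 of 29 were higher (median 0.17, adjusted p = 0.172, but 0.00789 without miR-148a-3p replicate 1 and 0.0438 without control replicate 2), with AURKB, the kinase of the chromosomal passenger complex, at 0.45 (SE 0.19) and CCNB2, a B-type cyclin, at −0.59 (SE 0.26). These calls with 1 library left out use the preset correlation of 0.01. The correlations estimated from all 6 libraries were 0.526 for the histones and 0.204 for the G2/M genes, and both lists then had camera adjusted p = 0.682.

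**Figure D2:**
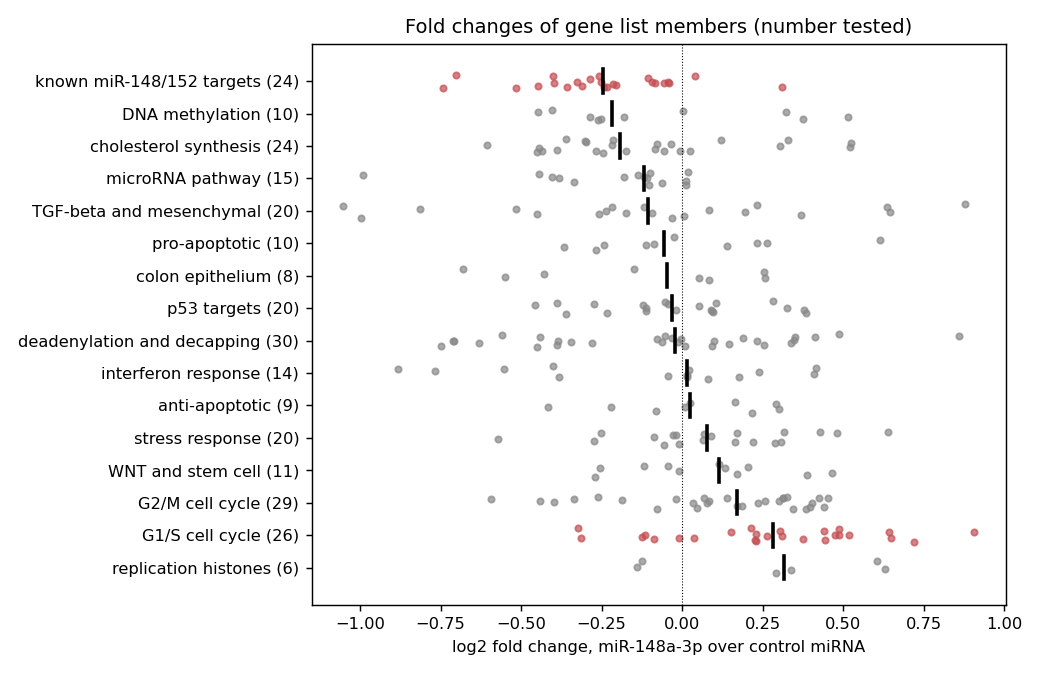
Fitted log2 fold changes of every tested member of the 16 gene lists, with the number tested in brackets and the median of each list as a bar. The lists past the threshold with a preset correlation are in red, and the known targets (median −0.25) and G1/S genes (median 0.28) are those lists.

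The remaining lists did not pass. Of the microRNA pathway genes 12 of 15 were lower (median −0.12, camera adjusted p = 0.0900, and 0.0409 without control replicate 3; from all 6 libraries, 0.682 with an estimated correlation and 0.284 with fry). Among them was XPO5, the nuclear export receptor of microRNA precursors, at 52.6 ± 15.3 CPM with the control and 26.0 ± 4.52 CPM with miR-148a-3p (−0.99, SE 0.32). Of the cholesterol synthesis genes 18 of 24 were lower (median −0.19, adjusted p = 0.263, and 0.0337 without control replicate 1; from all 6 libraries, 0.682 with an estimated correlation and 0.634 with fry), with HMGCS1 at −0.61 (SE 0.18) and FDPS at 0.52 (SE 0.20). The stress response genes had 12 of 20 higher (median 0.08, adjusted p = 0.231), led by the serine synthesis enzyme PHGDH at 0.64 (SE 0.20). In the TGF-beta and mesenchymal list, 12 of 20 were lower (median −0.11, adjusted p = 0.520), with SMAD7 at −1.05 (SE 0.43), SKIL at −0.81 (SE 0.28), SMAD3 at 0.88 (SE 0.33) and TGIF1 at 0.64 (SE 0.29). DNA methylation genes had a median of −0.22 (6 of 10 lower, adjusted p = 0.520), with MBD2, a reader of methylated DNA, at −0.45 (SE 0.20). The colon epithelium list, with KRT8 at −0.55 (SE 0.21), had adjusted p = 0.348.

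The p53 targets (adjusted p = 0.843), WNT and stem cell genes (0.762), anti-apoptotic (0.843) and pro-apoptotic genes (0.989) and interferon response genes (0.603) had medians within 0.12 of 0. MCL1, an anti-apoptotic BCL2 protein, was at −0.42 (SE 0.19), and CDKN1A, the p53-induced cyclin kinase inhibitor, at −0.27 (SE 0.18). Interferon genes had a median of 0.01 and a mean of −0.12, and pro-apoptotic genes a median of −0.06 and a mean of 0.01, so their sign depended on the measure. Across the 16 lists, DDX6 was the 1 member that passed adjusted over the list alone.

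Blood cell markers were scarce in all mRNA libraries, and the small RNA library was not checked for cell types. The blood cell markers summed to 5, 4 and 4 counts in the control libraries and 14, 2 and 0 with miR-148a-3p, with 0 genes tested. Fibroblast and endothelial markers summed to 85, 34 and 55 counts and to 83, 28 and 39, with COL1A1 the 1 gene tested (−0.31, SE 0.31). COL1A1 held most of these counts, with 83, 32 and 50 in the control libraries and 74, 27 and 38 with miR-148a-3p. It was not scarce, at 58.1 ± 21.3 CPM with the control and 47.8 ± 15.3 CPM with miR-148a-3p. Colon epithelium genes summed to 2170, 1574 and 1752 counts and to 2920, 1469 and 1083. Most of these came from KRT18, with 1320, 908 and 998 counts and with 1757, 831 and 594. Of the 23 genes of that list, 13 were counted in at least 1 library and 8 were tested.

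In wild-type HCT116 cells, miR-148a-3p was among the most abundant microRNAs. It made up 6.99% of all microRNA counts (253510 of 3627859, Wilson 95% interval 6.96% to 7.01%) and ranked 3 among 1023 names. It is made from MIR148A on chromosome 7, from 25949919 to 25949986. Its 5' end, which sets the seed, lay at the annotated position in 99.9% of its counts, and both ends did in 99.4%. The 3p arm held 99.7% of the counts of both arms, 354 times the 716 counts of miR-148a-5p. The microRNAs that share its seed were lower, with miR-148b-3p at 7365 counts (0.203%) and miR-152-3p at 189 counts (0.00521%), so that miR-148a-3p made up 97.1% of the family's counts.

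The most abundant name was miR-21-5p at 32.4% of counts (interval 32.3% to 32.4%), followed by miR-7-5p at 14.1%. After miR-148a-3p came miR-151a-3p (4.87%), miR-3529-3p (4.70%), miR-100-5p (4.17%), let-7i-5p (3.51%), let-7a-5p (1.83%), let-7f-5p (1.46%) and miR-92a-3p (1.10%). These 10 names held 75.1% of all counts. The counts of microRNAs with several genomic loci may hold each read more than once, and dividing by the number of RefSeq loci, with the 3 most abundant antisense names left out, gave miR-148a-3p 8.88% and rank 2. Less abundant names with mirrored counts were kept. On the same scale miR-7-5p, which has 3 loci, had 5.97%.

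**Figure D3:**
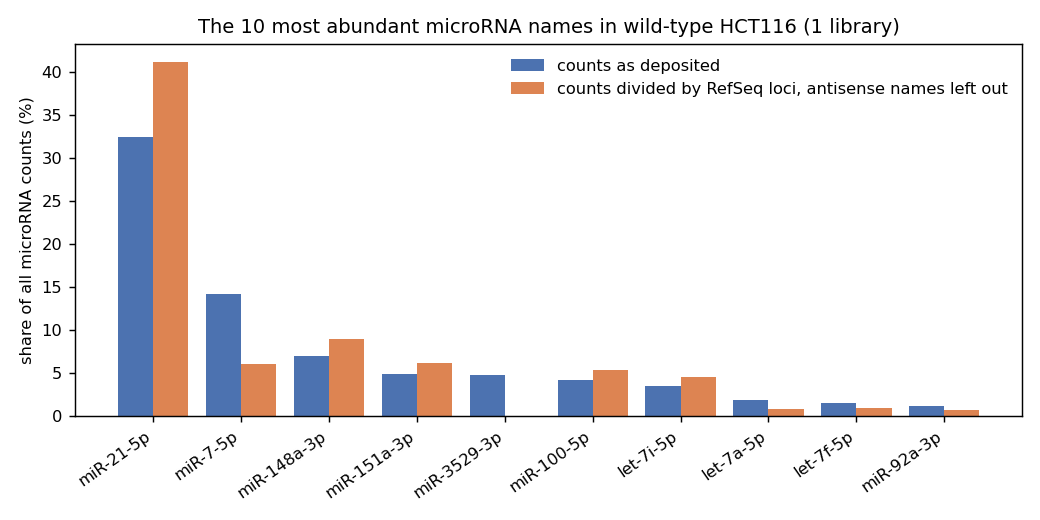
Share of all microRNA counts (%) of the 10 most abundant names in the wild-type library, as deposited (blue) and with counts divided by the number of RefSeq loci (orange, no bar for the antisense name miR-3529-3p). miR-148a-3p has 6.99% and 8.88%, and miR-7-5p 14.1% and 5.97%.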

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

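The mirrored-count test and the search for further mirrored names were chosen after the counts were seen; the share of even counts was predicted before it was computed, after the mirrored counts had been seen.

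In the small RNA library of wild-type cells, which no comparison between groups uses, 3 microRNA names had high counts although they lie antisense to abundant microRNAs: miR-3529-3p with 170478 counts (MIR3529, chromosome 15, 88611847 to 88611924, within MIR7-2), miR-103b with 28796 (within the MIR103A1 and MIR103A2 spans) and miR-3074-5p with 17071 (overlapping MIR24-1). These stand far above the 3 counts that a count of 0 allows, and no control library was analysed here for them. A search of all names with at least 1000 counts and overlapping loci found 8 mirrored pairs, these 3 and 5 less abundant ones, also above 3 counts: miR-3184-5p with 11611 counts (mirrored in miR-423-3p), miR-3158-5p with 4280 (in miR-3158-3p), miR-3184-3p with 2808 (in miR-423-5p), miR-203b-5p with 1922 (in miR-203a-3p) and miR-374c-3p with 1660 (in miR-374b-5p). Sense over antisense counts were 3.00 for miR-7-5p, which has 3 loci, 2.00 for miR-24-3p, with 2, and 1.00 for miR-103a-3p, with 2 loci each.

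Separate transcripts of the antisense strand were argued against, since 99.8% of the counts of the 3 antisense names equalled the sense count at the mirrored ends, per locus, within 2% and 1 count. A candidate explanation is that reads were counted on both strands and once per matching locus. It predicted even counts in over 90% of isoforms with 2 loci (the 3 antisense names and their partners left out, at least 10 counts each). The share was 87.3% (Wilson 95% interval 81.1% to 91.6%), short of that bound but above the 49.0% of isoforms with 1 locus. The mirrored names miR-3158-3p and miR-3158-5p (8 isoforms each, all even) were kept, so isoforms are not all independent and the interval may be too narrow. For isoforms with 3 loci no prediction was written. Their counts were divisible by 3 in 78.2%, against 31.6% of isoforms with 1 locus. The explanation stays open, since its written bound was not reached.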

How the results depend on the processing

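The offsets for gene length and chromosome, the summed reads of paired genes and the division of microRNA counts by loci were chosen after the data were seen. Over 72 named genes, 1134 of 1154 alternative values kept direction and side of the threshold, 16 moved past it and 4 reversed. Most of these genes lay far from the threshold, so keeping their side of it says little about stability. The 16 that moved were values of ANXA2, RPL17-C18orf32, METRN, GPX4 and PITX1. MORF4L1 passed under each alternative, with log2 fold changes of −1.89 to −1.41 and adjusted p up to 0.0141 with 1 library left out. Over the lists, 150 of 176 values were kept, 9 weaker, 5 stronger and 12 reversed. Genes past the threshold (1, with 1 lower and 0 higher) numbered 2 with DESeq2 (2 lower), 3 with limma-voom (3 lower), 18 without the count filter (11 lower, 7 higher), 2 after thinning (2 lower), 3 with offsets (3 lower), and 1 to 26 with 1 library left out (1 to 22 lower, 0 to 4 higher); the cause was not tested. Of the lists, 2 passed, and 0 with an estimated correlation, 0 with fry and 0 to 4 with 1 library left out. With the replicate block 3 genes passed (MORF4L1, ANXA2 and RPL17-C18orf32, 3 lower) and 2 lists. Same-numbered libraries deviated with correlations of 0.173, 0.114 and −0.001, against −0.169 to 0.042 for differently numbered ones. Replicates 1 and 2 thus correlated best with their own number, while control 3 correlated best with miR-148a-3p replicate 2 (0.039). With 3 libraries in each group, pairing by replicate number is neither shown nor excluded.

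With 1 library left out, the direction reversed for BIRC6 (−0.474 to 0.159), PMAIP1 (−0.033 to 0.392), H1-2 (−0.290 to 0.089) and EPHB3 (−0.0072 to 0.633). It also reversed for the anti-apoptotic (−0.12 to 0.245), p53 (−0.054 to 0.053), pro-apoptotic (−0.227 to 0.116), TGF-beta (−0.246 to −0.035, by the test's direction) and WNT lists (−0.047 to 0.104). For the pro-apoptotic list the test's direction also turned with the replicate block (median difference −0.058) and with fry (−0.052), while the median difference kept its sign. The median difference also changed sign for the deadenylation and decapping list (−0.077 to 0.025) and the interferon list (−0.223 to 0.015), though not the test's direction. The cause was not tested. The share of miR-148a-3p was 10.3% without miR-21-5p, 6.95% for its most abundant isoform, and 8.88% per locus, which follow from the changed numerator or denominator; a share of all counts in the library has the same denominator as the reported value. The seed site comparison was not run because transcript sequence was not used here. At these depths and numbers of libraries, 43.6% of genes simulated at a log2 change of 1 were called, among many changed genes. With fewer changed genes the adjusted threshold is stricter, so that share may be too high for this comparison.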

Other observations

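The tests of gene families, microRNA families and microRNA ends, and for chromosome 19 those of 1 library and of the treatment, were chosen after the result was seen, as were the genes named here and the chromosomes and gene length as patterns; the splits, the tests of the known targets and the tests of length and low counts on chromosome 19 were laid down before their results.

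Of 4 gene families looked at after the fact, none passed against other genes by camera in limma, with adjusted p over the families of 0.310 to 0.968. Ribosomal protein genes had a median of 0.03 over 81 members, yet 11 were lower and 2 higher at an unadjusted p below 0.05 with edgeR, where 4.05 are expected in all by chance. Over all 8921 genes tested, 606 were below 0.05. An example, whose reads can be shared with processed pseudogenes, was RPS2 at 1005 ± 424 CPM with the control and 494 ± 79.8 with miR-148a-3p (log2 fold change −1.02, edgeR adjusted p = 0.169). The groups overlapped for RPS2. Proteasome genes had 27 of 36 higher (median 0.13), respiratory chain genes 51 of 80 (median 0.08) and zinc finger genes 69 of 142 (median −0.02). LLGL1, a cell polarity gene, was at −1.72 (SE 0.38, adjusted p = 0.169) and COTL1, an actin-binding protein, at −0.88 (SE 0.20, adjusted p = 0.169), both lower in 3 of 3 libraries. RPS2, LLGL1 and COTL1 were each called by edgeR without the count filter and without control replicate 1, and RPS2 also with offsets for gene length and chromosome.

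In the wild-type small RNA library, the let-7 family (9 names) held 7.95% of counts, the miR-200 family 2.39%, the miR-30 family 2.15% and the miR-17-92 cluster 1.53%. Of 114 names with at least 1000 counts, 7 had their most abundant 5' end off the annotated position, and 5 of these mirror a name with overlapping loci. The others were miR-29a-3p, with 52.1% of counts 1 base upstream, and miR-142-3p, with 48.9% 1 base downstream and 48.8% at the annotated end.

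The known targets were lower with miR-148a-3p, with a difference in medians of −0.244 (camera adjusted p = 0.0163, but 0.682 with an estimated correlation). With fry, which tests the members against no change, the adjusted p was 0.411. After offsets for gene length and chromosome the difference was −0.235 (bootstrap SE 0.064), near the −0.244 without them. For these libraries, this argues against a trend with both as its source. The bootstrap resampled genes as if independent, though the estimated correlation of the list was 0.100. Its SE may therefore be too small, and it measures no spread between libraries. Dependence on 1 library was borne out by a narrow margin: without control replicate 1 the difference was −0.111, above a bound of −0.12. That bound was set before this test, but from the uncorrected difference already seen. Transfection of miR-148a-3p is the biological explanation the design gives and is untested here, since a seed site comparison was not run.

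Genes on chromosome 19 had a median log2 fold change of 0.18 and lay 0.195 above other genes, those on chromosome 22 had 0.09, and those on chromosome 13 had −0.12; fold changes also correlated with gene length (Spearman −0.19 across genes, which are not independent replicates). The libraries of each group did not overlap in the mean of chromosome 19 genes (−0.136, −0.093 and −0.039 in the control, 0.080, 0.111 and 0.078 with miR-148a-3p, exact two-sided permutation p = 0.1, the smallest 3 against 3 can give). Gene length (the RefSeq span, introns included), 1 library and low counts were each argued against as the whole cause. The chromosome 19 difference was 0.152 after length offsets, at least 0.171 with 1 library left out and 0.199 among genes of at least 50 CPM. A bias with transcript length was not tested, since the gene spans give no exons. A base composition bias between libraries was not tested, for want of sequence, and may account for the pattern, as may the treatment; with 3 against 3 these cannot be told apart.

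The 6 libraries make 10 splits into 3 and 3, too few for a share under 0.05. As many genes past the threshold came from 3 of the 10 splits (1 in the real split, at most 1 in the others), and as many lists from 5 (2 in the real, at most 4 in the others). The known targets reached as small a camera p in 2 splits (0.00204 in the real, 5.93e-04 the smallest other) and the G1/S genes in 3 (2.67e-04 in the real, 2.44e-12 the smallest other). That smallest G1/S p came from the split that set control replicates 1 and 3 with miR-148a-3p replicate 1. By the list's means, it set the 3 lowest libraries (−0.435, −0.057 and −0.275) against the 3 highest (0.069, 0.351 and 0.347). A small p follows from that order. Control replicates 1 and 3 stayed together there, as did miR-148a-3p replicates 2 and 3, so a group difference enters it too. That split therefore cannot tell a structure of the libraries from the groups. These p-values use the preset correlation, while the correlation estimated for the G1/S genes was 0.354.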
